A study of Dinoroseobacter shibae with 8 samples.

How the data were processed

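The data are 8 single-colour Agilent arrays, 1 per sample, of Dinoroseobacter shibae DFL12T cultured with or without phage R2C and sampled early or late. Per the labels' protocols, cells were pelleted and frozen, total RNA was extracted, given poly(A) tails, copied from an oligo(dT) primer, amplified and labelled with Cy3. Because the amplification starts from an added tail, levels of different genes are not compared with each other. Per the file headers, the authors scanned the arrays and extracted spot intensity with Agilent Feature Extraction 11.5.1.1, which gave a background-subtracted processed signal per spot and quality marks. These deposited intensity values are not normalized between arrays. The deposited table of the whole series holds the submitters' own values on a log2 scale. Its column medians were 9.51, 9.52, 9.54 and 9.52 for infected early replicates 1 and 2 and uninfected early replicates 1 and 2, and 9.50, 9.52, 9.52 and 9.50 for the late groups in that order. Each column correlated with the log2 signal of its own array at r from 0.981 to 0.995, with a slope from 0.938 to 0.987, and lay above quantile-normalized signals by a median of 0.19 to 0.22. The scale and direction follow from this, while the background correction and normalization behind that table are not given in the sources used here. The submitters' processing notes name limma without a version or model.

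Groups were taken from the sample titles and infection labels. The series design states that the replicates are biological. The late samples carry 140 min in their titles and source names and 120 min in their time label, and this conflict was left open.

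Control spots were left out, which left 15208 spots for 4219 genes, 1 probe per gene in 3 to 4 spots. The processed signal was log2-transformed, and the 75th percentile of each array was subtracted. Lower and higher levels are thus relative to that percentile of the same array. Spots marked as non-uniform or population outliers were then left out, and the spots of a gene were averaged. For 2 gene values every spot was marked, and those values are missing. A gene was tested where at least 0.5 of its spots were well above background on both arrays of at least 1 group, which kept 4131 genes. The model had the 4 group means on all 8 arrays and was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom, 5.25 prior degrees of freedom). The median residual SD over genes was 0.19 on the log2 scale. Comparisons were infected minus uninfected at each time, the difference between these, and late minus early in each condition. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the tested genes. No gene past the threshold was below background throughout a group (0 in each comparison), so no fold is a lower bound. Replicon sets of at least 5 genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. A run is a series of consecutive numbers on 1 accession whose genes passed the threshold in 1 direction.

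The steps were tested on simulated data over 4129 genes, with each gene's spread taken from the moderated SD that eBayes gave for these arrays. That SD is drawn towards a common value, so the simulated spreads vary less between genes than the residual SDs. The simulated noise was normal and independent between genes and between arrays, in a single draw per comparison. Correlation of replicates between the times and shared changes of neighbouring genes were left out, so the rates may differ for these data. For the early infection comparison, 13.4% of genes changed 1.41-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 11 false calls of 141. For the late infection comparison the shares were 5.97%, 83.6% and 98.5%, with 7 false calls of 132, and for time without phage they were 8.96%, 85.1% and 100%, with 9 of 138. Changes well under 2-fold are thus mostly out of reach with 2 arrays per group.

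The rule for naming genes was set before the data were examined. For the infection comparisons at each time it asked for annotated genes first. It then asked for the 2 largest increases and 2 largest decreases among unannotated genes past the threshold whose arrays did not overlap. As no identifier matched an annotated gene, only the second part applied. For the other comparisons the rule asked for more genes in each direction. Giving 2 in each direction over time, and the lowest p in each direction where no gene passed, departs from it. Lists of processes (ribosome, flagellum, photosynthesis, DNA repair and others) had been set before the data were examined, and none could be applied, since 0 identifiers matched a named gene. Genes were not named from their place in a reference annotation.

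All 8 arrays lay on 1 slide with 1 scan date, so neither could be a block. Early arrays filled row 1 of the slide and late arrays row 2, infected cultures columns 1 and 2, and uninfected cultures columns 3 and 4. The signal of a spike-in control over the 75th percentile was 0.443 and 0.662 on uninfected early and late replicate 1. It was 2.02 to 5.36 on the other arrays. The slope of the extraction software's spike-in fit was 0 on infected replicate 2 and uninfected replicate 1 at both times. Elsewhere that slope was 0.90 to 0.91, and the reason is not known. The crossed pairing described below makes the same split of the arrays. Replicate numbers recur in all groups. Alternatives covered normexp background correction, quantile and median scaling, filters on dim genes, the submitters' processed values, limma-trend, an added 2-fold minimum, the replicate number as a block, only the arrays of 1 time, and each array left out in turn. Normexp was run on median signals, because the files used here hold no mean signal. It adds an offset of 50 intensity units, which by construction shrinks log2 differences that involve low signals. The brightest probe per gene was no separate alternative, as each gene had 1 probe.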

Results

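Gene expression was measured in the marine bacterium Dinoroseobacter shibae DFL12T, an alphaproteobacterium of the Roseobacter group, grown with or without the phage R2C. The series asks how the bacterium's transcript levels differ when phage is present. RNA was taken at 2 times, and each of the 4 combinations of infection and time had 2 biological replicates, so 8 arrays were compared. The early time was 60 min by every label. The late time was 140 min by the sample titles and 120 min by the time label of the same samples, so the groups are called early and late here. The arrays carried 4219 genes with 3 to 4 replicate spots each, and 4131 genes entered the tests. Between 97.6% and 97.8% of the spots lay well above background on each array. The 75th percentile of the signal ranged from 919 (uninfected late replicate 1) to 4510 intensity units (infected early replicate 1), and no spot was saturated. Replicates correlated across genes at r from 0.978 to 0.991. The number of arrays, 2 per group, limits the precision of every value.

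Gene identities are limited to the array's own identifiers. Each identifier joins a sequence accession to a running number, and 0 of them matched a named gene in the reference table, so the files used here do not pair these genes with names or functions. The accession with 3614 genes on the array, NC_009952.1, is the chromosome in the reference table. A further 5 accessions carried 191, 132, 61, 61 and 73 genes of the array. They are called here replicons by these counts of array genes, which need not be their full sizes. Of those with 61 genes, the one described below had numbers up to 111 and the other up to 68. None of these 5 is listed by accession in the reference table, which lists replicons other than the chromosome by name. Gene 1781, for example, is NC_009952.1_gene_1781. Genes below are chromosomal unless stated otherwise.

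At the early time the infected cultures differed from the uninfected ones mainly by lower transcript levels of a small set of genes. Of the 4131 tested genes, 42 were lower and 1 was higher in infected cultures (limma, Benjamini-Hochberg adjusted p under 0.05), and 40 of the lower genes differed by at least 2-fold. The median difference of the 42 genes was -2.15 on the log2 scale, with a range from -7.65 to -0.87. The largest decrease was that of gene 1781, which was 201-fold lower with phage (log2 difference -7.65 ± 0.16, SE; limma adjusted p = 1.086e-08). Its level, relative to the 75th percentile of each array, was -4.60 ± 0.02 (SD, n = 2) in infected and 3.05 ± 0.17 in uninfected cultures. Gene 1780 was 147-fold lower (-7.20 ± 0.17, SE; limma adjusted p = 1.352e-08). With normexp on median signals the differences were -6.88 for gene 1781 and -6.24 for gene 1780. Both genes belong to a run of 4 consecutively numbered genes that were all lower, with a median of -6.29. A longer run of 14 consecutive numbers was lower too, with a median of -2.26 and values from -3.38 to -1.10. In all, 25 of the 42 lower genes lay in 5 runs of at least 2 consecutive numbers. By replicon, 34 of the lower genes were on the chromosome, 5 among the 131 tested genes of the 132-gene replicon and 3 on the 73-gene replicon. The only higher gene, gene 1111, was 1.96-fold higher with phage (0.97 ± 0.19, SE; limma adjusted p = 0.0496). Gene 1111 lost its call in 14 of 21 alternatives, among them every refit without an infected array of either time or without an uninfected early array. At an unadjusted p under 0.05, 75 genes were higher and 176 were lower. With only the 4 early arrays in the model, 70 genes passed. A block that sets replicate 1 of 1 condition with replicate 2 of the other (crossed pairing) gave 17 higher and 68 lower genes.

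**Figure D1:**
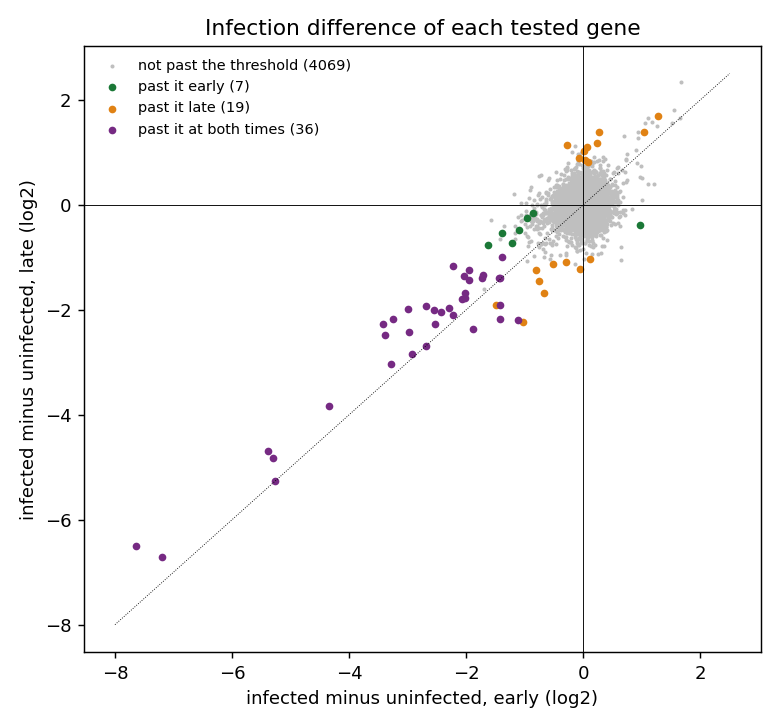
Infected minus uninfected difference (log2) of each of the 4131 tested genes at the early time (horizontal axis) and the late time (vertical axis), with 1 point per gene, coloured by whether its adjusted p was under 0.05 early, late or at both times. The 36 genes past the threshold at both times all lie at the lower left, and the dotted line marks equal differences.

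At the late time 45 genes were lower and 10 were higher in infected cultures. All 45 lower genes and 7 of the higher ones differed by at least 2-fold. The median difference of the lower genes was -1.96, and that of the higher genes was 1.13. Gene 1780 was 104-fold lower with phage (log2 difference -6.71 ± 0.17, SE) and gene 1781 was 90.5-fold lower (-6.50 ± 0.16, SE), each with a limma adjusted p = 2.615e-08. With normexp on median signals the differences were -5.24 for gene 1780 and -5.57 for gene 1781. The level of gene 1780 was -5.42 ± 0.15 (SD, n = 2) in infected and 1.29 ± 0.17 in uninfected cultures. The run of 4 genes that holds both was again lower throughout, with a median of -5.66. Of the run of 14 genes, 13 were lower, with a median of -2.01. In all, 28 of the 45 lower genes lay in 7 runs of at least 2 consecutive numbers. The largest increase was that of gene 583, which was 3.24-fold higher with phage (1.70 ± 0.33, SE; limma adjusted p = 0.0436). Gene 1848 was 2.62-fold higher (1.39 ± 0.19, SE, limma adjusted p = 0.00568). Its mean level was -1.98 early and -1.96 late in infected cultures, and -2.25 early and -3.35 late in uninfected ones. Gene 583 lost its call when any of the 4 late arrays was left out (adjusted p from 0.0824 to 0.322), without the filter on dim genes (adjusted p = 0.0648) and with normexp on median signals (adjusted p = 0.0520). Gene 1848 lost its call without infected late replicate 1 (adjusted p = 0.0553) or replicate 2 (adjusted p = 0.0517). With both uninfected replicate 1 arrays left out, which had a weak spike-in signal, 29 genes were lower and 0 were higher, and both genes 583 (1.91) and 1848 (1.38) lost their calls at a similar size. With normexp on median signals 36 genes passed. The crossed pairing gave 35 higher and 54 lower genes. With the replicate number as a block gene 583 lost its call (limma adjusted p = 0.0844).

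The differences at the 2 times concerned largely the same genes. Of the 42 genes lower early and the 45 lower late, 36 were lower at both times, against 0.458 expected for independent lists (Fisher's exact test, two-sided, p = 1.320e-73). Their median difference was -2.36 early (5.15-fold lower) and -2.08 late (4.21-fold lower). All 42 genes that were lower early had a negative difference late, and 44 of the 45 genes that were lower late had a negative difference early. No gene was higher at both times. Across all tested genes the early and late differences correlated with Pearson's r = 0.62 and Spearman's rho = 0.18, and without the genes called at either time r was 0.26 over 4069 genes. These correlations are across genes, which are not independent replicates. The early and late comparisons share no array, but replicate deviations correlated between the times within a condition (r = 0.387 with phage and 0.682 without). Both comparisons also take each gene's spread from the same fit, and genes in runs are not independent of each other. The expected overlap and the p take comparisons and genes as independent and leave these links out.

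**Figure D2:**
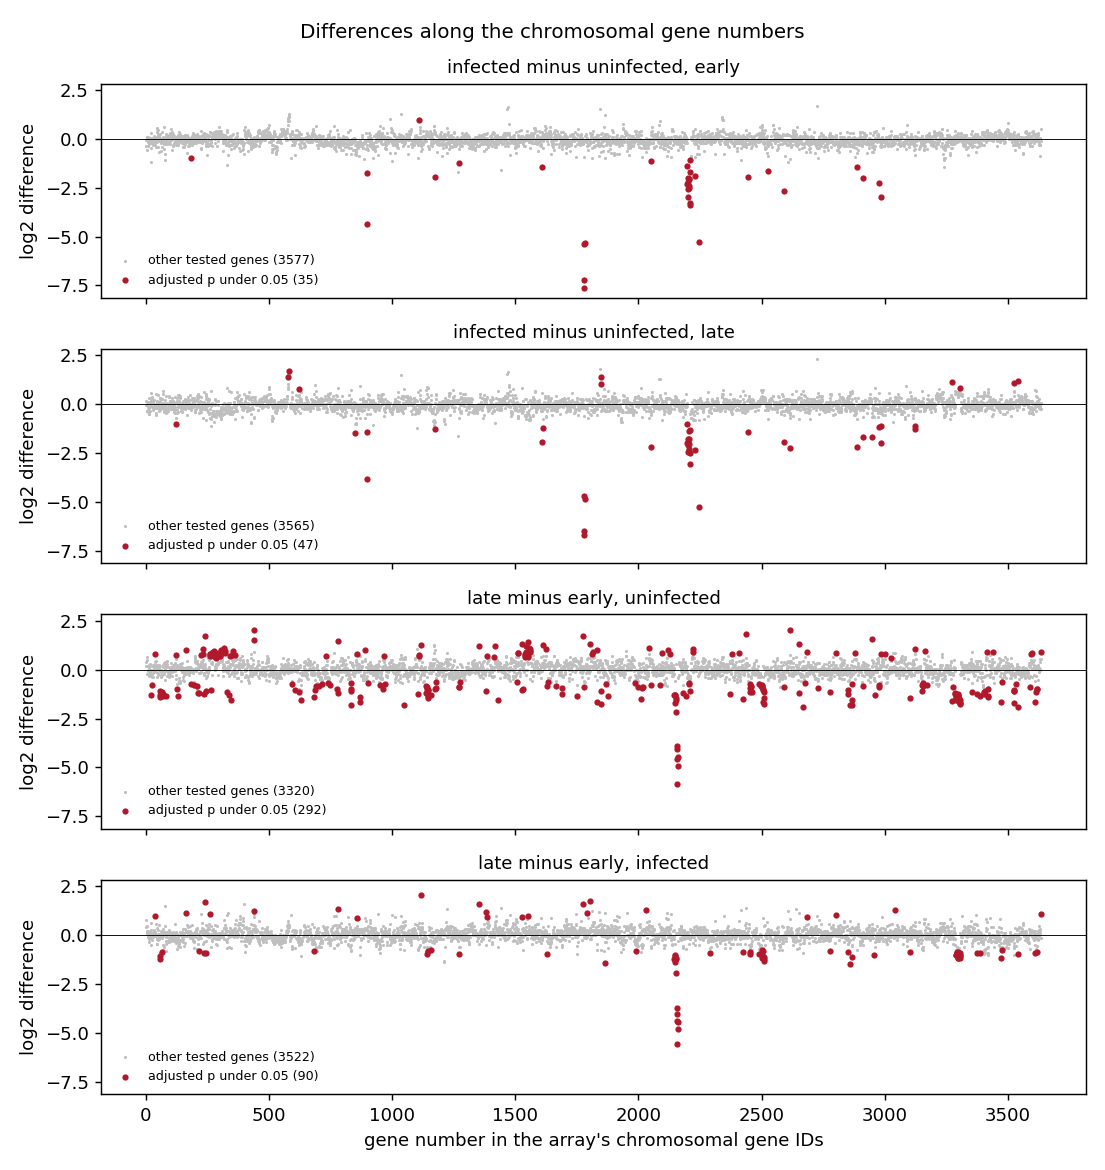
Log2 difference of each tested chromosomal gene against the number in its array identifier, for infected minus uninfected at the early and late times and for late minus early in uninfected and infected cultures, with genes of adjusted p under 0.05 in red. The infection differences gather at a few numbers, with the lowest at -7.65 early, and a run of 6 genes with a median of -4.31 stands out over time in uninfected cultures and again in infected cultures.

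Whether the infection difference itself changed between the 2 times was tested as an interaction. With limma no gene passed (0 of 4131; smallest adjusted p = 0.634), while 131 genes were higher and 148 lower at an unadjusted p under 0.05. The lowest unadjusted p in the positive direction was that of gene 3275, whose difference was 1.42 ± 0.24 (SE) more positive late (adjusted p = 0.634). In the negative direction gene 1111 had a value of -1.36 ± 0.26 (SE; adjusted p = 0.634). With infection state and replicate number together as a random block 4 genes passed. Without that block, genes called at only 1 of the 2 times are not shown to differ between the times.

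Without phage, 106 genes rose and 201 fell between the early and the late time (limma). Of these, 35 rose and 130 fell by at least 2-fold. The largest decrease was that of gene 2158, which fell 56.9-fold (log2 change -5.83 ± 0.26, SE; limma adjusted p = 4.767e-06). Gene 2159 fell 30.7-fold (-4.94 ± 0.18, SE; limma adjusted p = 1.843e-06). With normexp on median signals these changes were -4.31 and -3.99. Both lie in a run of 6 consecutively numbered genes that fell with a median of -4.31. The longest run, of 22 consecutive numbers, fell with a median of -1.46. Among the genes that rose, gene 2616 was 4.07-fold higher late (2.02 ± 0.28, SE; limma adjusted p = 0.00258) and gene 438 was 4.02-fold higher (2.01 ± 0.20, SE; limma adjusted p = 0.000800). In all, 114 of the 201 genes that fell lay in 33 runs, and 50 of the 106 that rose lay in 16 runs, of at least 2 consecutive numbers. The total of 307 genes became 117 without uninfected early replicate 1 and 113 without uninfected early replicate 2. With both uninfected replicate 1 arrays left out it was 6, with 0 that rose and 6 that fell, and genes 2616 (adjusted p = 0.111) and 438 (adjusted p = 0.0658) lost their calls, although their changes were 2.05 and 2.07. That refit leaves 1 array per uninfected group. With infection state and replicate number together as a random block it was 794, with 381 that rose and 413 that fell.

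With phage, 24 genes rose and 70 fell between the times, 17 and 32 of them by at least 2-fold. Gene 2158 fell 47.8-fold (log2 change -5.58 ± 0.26, SE; limma adjusted p = 7.111e-06) and gene 2159 fell 28.4-fold (-4.83 ± 0.18, SE; limma adjusted p = 2.273e-06). With normexp on median signals these changes were -4.19 and -3.97. The run of 6 genes that holds both fell with a median of -4.20. Gene 1119 rose 4.15-fold (2.05 ± 0.27, SE; limma adjusted p = 0.0105) and gene 1804 rose 3.36-fold (1.75 ± 0.27, SE; limma adjusted p = 0.0164). Gene 1119 lost its call without infected early replicate 2 or either infected late array, and gene 1804 without either infected early array or infected late replicate 1. The total of 94 genes was 15 and 14 without infected early replicate 1 and replicate 2, 7 and 22 without infected late replicate 1 and replicate 2, 48 without either uninfected early array and 155 without either uninfected late array. With both uninfected replicate 1 arrays left out it was 30, with 10 that rose and 20 that fell, and gene 1804 lost its call (1.75, adjusted p = 0.0540). With the random block it was 487, with 215 that rose and 272 that fell. On the slide, rows coincided with time and pairs of columns with infection, so position and group cannot be told apart across the whole slide.

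**Figure D3:**
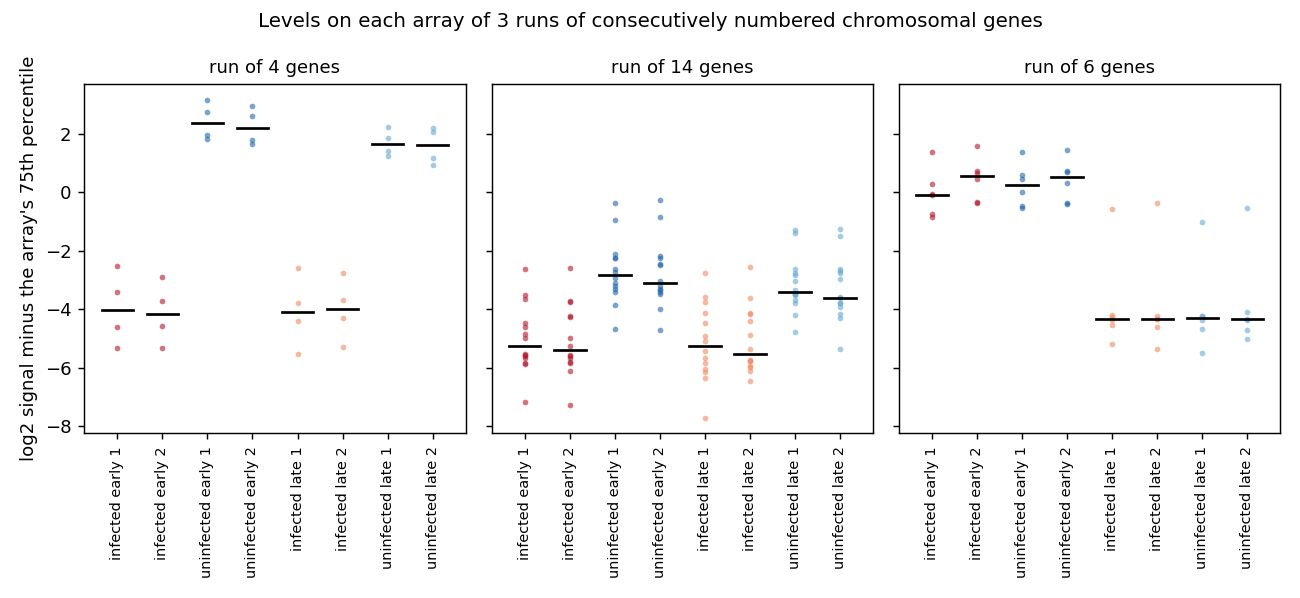
Level of each gene (log2 signal minus the array's 75th percentile) on each of the 8 arrays, for the runs of 4, 14 and 6 consecutively numbered chromosomal genes, with 1 point per gene and a bar at the median of the run. The runs of 4 and 14 genes lie lower on all 4 infected arrays, and the run of 6 genes lies lower on all 4 late arrays.

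Genes were also compared as sets by replicon, the only grouping the identifiers allow. At the early time, genes of the 191-gene replicon lay higher with phage (median 0.16; camera adjusted p = 3.073e-07), as did those of a 61-gene replicon (median 0.10; camera adjusted p = 0.000461). Genes of the 73-gene replicon lay lower (median -0.20; camera adjusted p = 0.000231). None of these 3 calls held with an estimated correlation (adjusted p = 0.358, 0.358 and 0.471). Fry sets a replicon's genes against no change and not against other genes. Its directional test gave adjusted p = 0.372, 0.272 and 0.302 for these 3, and its mixed test, which asks for changes in either direction, gave 0.345, 0.473 and 0.00321. The mean shift of the 191-gene replicon against all other genes was 0.22, and it was 0.11 without uninfected early replicate 1 and 0.32 without replicate 2. That of the 61-gene replicon was 0.19, and it was 0.12 without uninfected early replicate 1. On the 191-gene replicon 0 genes passed the test of single genes, and on the 73-gene replicon 3 did. At the late time no replicon was called (camera, smallest adjusted p = 0.968; 0 of 6 at an unadjusted p under 0.05), while 5 were called without uninfected late replicate 1 and 1 without uninfected late replicate 2. By fry at the late time, against no change, 0 of 6 passed the directional test, and the mixed test gave adjusted p = 5.010e-06 for the 132-gene replicon and 7.126e-05 each for the chromosome and the 73-gene replicon. No probe is assigned to phage R2C by the array's names, so no probe checks the infection labels. A further accession, whose organism the files do not give, had 86 probes. Of these, 80 were well above background on no array and 1 on all 8, and 0 were well above background on both arrays of an infected group and neither array of the matching uninfected group.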

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

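The 4 results in this part were chosen because a test found that the infection difference of a replicon's genes differed between the late and the early time. Values are the mean over the replicon's genes minus the mean over all other genes, on the log2 scale. For the 191-gene replicon the late minus early infection difference was -0.20 (camera adjusted p = 9.501e-05; adjusted p = 0.445 with an estimated correlation), and without uninfected late replicate 2 it was 0.014 (adjusted p = 0.789). For the 61-gene replicon that lay higher with phage at the early time it was -0.20 (camera adjusted p = 0.00274; adjusted p = 0.405 with an estimated correlation), and without uninfected late replicate 2 it was -0.074 (adjusted p = 0.407). For the 73-gene replicon it was 0.23 (camera adjusted p = 0.000138; adjusted p = 0.445 with an estimated correlation), and without uninfected late replicate 2 it was 0.13 (adjusted p = 0.184). For the 132-gene replicon it was 0.089 (camera adjusted p = 0.0390; adjusted p = 0.445 with an estimated correlation). That call was also lost with the submitters' processed values (adjusted p = 0.0905), without infected early replicate 2 (0.220), uninfected early replicate 2 (0.0794), infected late replicate 2 (0.0699) or uninfected late replicate 2 (0.228). Other single arrays also moved these values: without uninfected early replicate 1 the value of the 191-gene replicon was -0.091, without uninfected late replicate 1 it was -0.41 and that of the 61-gene replicon -0.32, and without infected early replicate 2 that of the 132-gene replicon was 0.058. Fry, which sets each replicon's genes against no change and so does not test these differences from other genes, gave adjusted p = 0.428 in the directional test and 0.517 in the mixed test for each of the 4 replicons.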

How the results depend on the processing

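Normexp on median signals, the crossed pairing, the random block, the removal of both arrays with a weak spike-in signal and the keeping of outlier spots were chosen after seeing the data. The count of 36 genes lower at both times stayed within 1.5 times under all 22 alternatives (25 to 53; 31 to 38 with 1 array left out). Among 15 named gene results, 273 of 307 alternatives kept direction and threshold, 34 lost the threshold and 0 changed direction. For many of these alternatives the direction was fixed in advance. Named genes had arrays that did not overlap between the groups, so leaving arrays out could not reverse a difference. Filters, blocks and limma-trend leave the difference itself unchanged. No scaling moved the median of all genes by over 0.1.

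The early infection count of 43 became 70 with only the 4 arrays of that time (33 to 57 with 1 array left out). The late count of 55 became 36 with normexp on median signals and 29 without both arrays of weak spike-in signal (41 to 79 with 1 array left out). An added 2-fold minimum lowered the counts over time from 307 to 165 without phage and from 94 to 49 with phage, by its construction. The offset in normexp also shrinks differences that involve low signals. How much of its lower counts and smaller differences comes from the offset was not tested. Without both arrays of weak spike-in signal these counts were 6 and 30, and with 1 array left out they ran from 113 to 359 and from 7 to 155. Infection state with replicate number as a random block (estimated correlation 0.505) gave 794 and 487, and 4 genes for infection by time in place of 0. Of the 3 replicons called early and the 4 called for infection by time, 0 were called with an estimated correlation; 0 passed fry's directional test, which sets a replicon against no change and cannot remove a difference from other genes. With 1 array left out these counts ran from 3 to 5 and from 0 to 6, and the late count from 0 to 5. The shift of the 191-gene replicon for infection by time ran from -0.41 to 0.014. A lone array left in a group was assumed to vary like the other groups, and beyond fewer arrays the cause of these moves was not tested.

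Replicate numbers were not taken to pair infected with uninfected cultures, as deviations from the group means correlated at -0.308 early and -0.0125 late. Infected early and uninfected late deviations correlated at -0.297, and uninfected early and infected late deviations at -0.00756. The clearly negative values thus both involve the infected early arrays. Negative values go with pairs whose numbers are crossed, and whether the cultures were paired in that way stays open. Between the times the correlations were 0.387 with phage and 0.682 without. Within a condition the number thus goes with something shared by both times. Each replicate number also kept its slide column at both times within a condition, so culture and column cannot be told apart. Both arrays with a weak spike-in signal lay in column 3. The main model takes the arrays of both times as independent and leaves this correlation out. With the replicate block the counts were 46 early, 56 late, 0 for infection by time, 319 and 116 over time without and with phage, 38 for genes lower at both times, and 3, 0 and 4 for replicons; genes 1111 (adjusted p = 0.0571) and 583 (adjusted p = 0.0844) lost their calls. The crossed pairing gave 85 early, 89 late, 0 for infection by time, and 434 and 183 over time. Normexp on mean signals, the brightest probe, slide or scan blocks and the alternatives for phage probes were not run, as the files used here hold no such column, second probe, second slide or probe named for the phage. Signal over background limits few genes, since 97.6% or more of the spots were well above background.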

Other observations

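Tests chosen only after the result was seen are those of a mislabelled array, of a response that builds up, of an earlier culture difference, of the arrays with a weak spike-in signal and of neighbouring numbers, and the overlap of the changes over time.

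The changes over time were shared in part by cultures with and without phage. Of the 201 genes that fell without phage and the 70 that fell with phage, 65 were shared, against 3.41 expected for independent lists (Fisher's exact test, two-sided, p = 6.654e-84, adjusted p = 1.331e-83). Of the 106 and 24 genes that rose, 19 were shared, against 0.616 expected (Fisher's exact test, two-sided, p = 4.293e-27, adjusted p = 4.293e-27). Both comparisons take each gene's spread from the same fit, and genes in runs are not independent of each other. The expected overlaps and the p leave this out. Of the 307 genes called without phage, 287 had the same sign with phage, while their median size was 1.02 without phage and 0.64 with phage on the log2 scale. A smaller size with phage follows in part from choosing these genes without phage, so the sizes do not show a difference. Across all tested genes the changes with and without phage correlated with Pearson's r = 0.67 and Spearman's rho = 0.45, and genes are not independent replicates. The 36 genes that were lower with phage at both times changed by a median of -0.45 over time in uninfected cultures, where 8 of them fell, and by -0.081 in infected cultures, where 0 fell. Among the genes lower with phage only late, genes 123, 1612, 2616, 2948, 2986 and 3124 rose in uninfected cultures. Genes 851 and 3125 and gene 68 of the 61-gene replicon with numbers up to 68 were not called there. Of the genes higher with phage late, genes 622, 1847, 1848, 3275, 3304, 3524 and 3540 fell in uninfected cultures. So did gene 53 of the 132-gene replicon, while genes 577 and 583 were not called. Both kinds of comparison share the uninfected late arrays, so these overlaps are not independent.

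For the 36 genes lower with phage at both times, a local defect of the slide would also lower the neighbours on the array. The 1575 spots adjacent to these genes' spots had a median difference of -0.030 early and -0.016 late. Over all tested genes the median was -0.042 early and -0.022 late. These medians argue against a defect common to most of the spots. A pooled median cannot exclude a defect at a few of them. The SD between a gene's replicate spots, with marked outlier spots left out, had a median of 0.076 (log2) over these genes. It was 0.060 over all tested genes. For most of these genes this argues against a defect at only some of a gene's spots. As a median it leaves a few genes open. A single mislabelled array is argued against by a test in which each array was placed with genes chosen from the other 7 arrays: the median distance from the midpoint towards its own condition was at least 0.859 on the log2 scale, with at least 97.2% of the genes on that side. A response that builds up over the infection stays open. The late minus early difference of the 51 genes lower at either time had a median of 0.35. With 1 array left out that median was 0.24 to 0.42, and the difference was smaller late for 36 of the 51. The infection difference of most of these genes thus did not grow. However, the genes lower at both times changed over time by a median of -0.45 in uninfected and -0.081 in infected cultures. The smaller difference thus goes with a fall in uninfected cultures, so this test cannot decide whether a response builds up in infected ones. A difference between the cultures that was there before the phage may also account for the set, and it stays open because 0 arrays come from a sample taken before the phage was added. An effect of phage R2C and an exchange of the infection labels between whole groups stay open as well.

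The run of 6 chromosomal genes that fell over time in both conditions was weighed next. A slide defect common to most of the run's spots is argued against by the 233 adjacent spots. Their median change was 0.073 without phage and 0.087 with phage. A pooled median cannot exclude a defect at a few of the spots. The SD between a gene's replicate spots had a median of 0.069 over the run, with marked outlier spots left out. For most genes of the run this argues against a defect at only some of a gene's spots. The run fell by similar medians without phage (-4.31) and with phage (-4.20). Time in culture stays open as the biological explanation.

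More genes passed the threshold over time without phage (307) than with phage (94). The arrays with a weak spike-in signal stay open as a source: with both left out the count without phage was 6 against 30 with phage, and with the other uninfected array of each time left out it was 57 against 30. Each refit leaves 1 array per uninfected group, and the 307 changes had a median size of 1.01 and 1.06 on the log2 scale, against 1.02 with all arrays. For each gene the changes of these refits average to the change with all arrays, on which the 307 genes were chosen. Similar sizes thus follow from the design and cannot decide whether the weak arrays are the source. Equal changes split by the threshold stay open too, since the ratio of the noise-corrected SD of changes with phage to that without was 0.777, and from 0.669 to 0.858 with 1 array left out. The interaction test called 0 genes, and 4 with infection state and replicate number together as a random block, so whether the conditions differ in these changes depends on that choice.

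Genes with neighbouring numbers may change together, as genes transcribed as a unit would; this is a hypothesis, since the files used here give no transcription units. Of the 34 chromosomal genes lower early, 20 had another lower gene at an adjacent number, and the highest of 100000 random draws was 8 (permutation test, one-sided, p = 1e-05, the smallest these draws can give). Of the 38 lower late, 23 did, against at most 10. Of the 194 that fell without phage, 112 did, against at most 49, and of the 98 that rose, 44 did, against at most 20. The same held for 38 of the 69 that fell with phage, against at most 15, while 0 of the 21 that rose with phage had such a partner (permutation p = 1). Over 7 such tests the adjusted p was 1.4e-05 for each of the first 5 and 0.022 for the genes higher late, of which 2 of 9 had a partner.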
